A study of Mus musculus with 9 samples.

How the data were processed

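Chromatin immunoprecipitation with sequencing (ChIP-seq) for the nuclear receptor NR4A2 was carried out on mouse heart ventricle, per the labels. The series holds 9 samples. Of these, 3 are ChIP libraries from hearts of Nr4a2-icTg mice, in which tamoxifen switches on an Nr4a2 transgene in cardiomyocytes, and 3 are ChIP libraries from littermates that carry the same inducible Cre recombinase, αMHC-MerCreMer, and serve as controls. All mice were 8 to 9 weeks old and were studied 3 days after 1 injection of tamoxifen at 40 mg/kg, per the labels. Each reaction used 30 µg of chromatin and 5.5 µg of antibody (clone 9D12), with 200 ng of fruit fly chromatin and 0.4 µg of an antibody against a fly histone as a spike-in, per the labels' protocols. The other samples (1 antibody test ChIP, 1 antibody test input and 1 pooled input) have no column in the table used and were not analysed here.

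The authors deposited 1 table of 16884 genomic regions with 1 column for each of the 6 mice. Alignment with BWA to build GRCm38 (mm10) is named in the submitters' processing notes. The peak caller, the way regions were merged, the counter and any filter are not given in the sources used here. The values deposited per mouse are in CPM (counts scaled to a common library size): every value was a whole multiple of the smallest value above 0 in its column (100% of values, tolerance 0.001 of a read), and columns summed to 989059 to 1009112. Whole reads could therefore be recovered from the CPM. The scaling factors left beyond the reads in regions, 0.991 to 1.01, were those that edgeR's TMM method gives on the recovered reads of the listed regions. The deposited CPM are thus relative to each library's own reads in the regions, and no spike-in factor enters that scaling. Whether reads were reduced in proportion to the spike-in before counting is not given in the sources used here. If they were, the recovered reads without scaling would be the spike-in comparison. A change shared by all regions cannot be seen in such values. The table also holds the authors' log2 fold change and log2 mean CPM per region, and the authors' p-value and FDR, per the file headers, with a call of up, down or unchanged. Columns were matched to mice by name, and no column of values was left unmatched.

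Recovered reads in regions numbered 984905, 1027394 and 549700 in the control libraries and 1035856, 637635 and 794382 in the NR4A2 libraries. At these depths 1 read was worth 0.955 to 1.81 CPM, and 3 reads were worth 2.86 to 5.43 CPM. The median region held 20 to 40 reads per library. Intervals on shares are 95% Wilson intervals. They cover counting error over regions only.

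The design fixed before the data were examined named edgeR for whole-number counts and limma for values already normalized. The values are CPM, so the test used was limma (version 3.58.1, in R 4.3.3) with trend and robust variance moderation on log2(CPM + 1), with genotype as the only term and no further scaling. Fold changes are differences of mean log2(CPM + 1). In regions with little signal the added 1 pulls them towards 0, while a single library near 0 can enlarge them. Regions with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. No region was filtered out. The adjusted p-values named in the results are from this fit unless another tool is named. On simulated reads with the means, depths and dispersions of these 16884 regions, limma recovered 39% of 100 regions changed by 1 on the log2 scale and 78% of 100 changed by 2, with 6 false calls. edgeR (version 4.0.16) recovered 41% and 83%, with 9 false calls. The simulation raised and lowered equal numbers of regions and scaled by the true depths. It therefore does not cover false lower calls that an excess of gains could bring about.

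Regions were placed against the protein-coding genes of the RefSeq annotation of GRCm38.p6, and against Gt(ROSA)26Sor, the locus of the knock-in. This gene table gives the span of each gene but neither its strand nor its exons. The distance to a transcription start that the design named was therefore replaced by the distance to the nearer end of a gene, so that exon, intron and promoter are not told apart. A region was assigned to every gene whose span, extended by 10 kb on either side, it touched, and 1 region can belong to several genes. Shares of regions within 1 kb of a gene end were compared with Fisher's exact test, two-sided. Regions are not independent replicates, so these p-values describe the called set.

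Gene lists were fixed before the data were examined: 21 lists with 535 entries, of which 534 matched a gene. For each list, genes with at least 1 higher region were compared with all 11155 genes that had a region, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 21 lists. The same was done for lower regions. Each list was also set against 10000 random lists matched on regions per gene, because a gene with many regions has more chances to hold a called one. The lists on published NR4A targets were drawn up from general knowledge and not from these samples.

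Regions named in the text follow a rule written before the data were examined. Part 1 takes the 10 genes with the highest log2 fold change among higher regions whose NR4A2 libraries all lie above all control libraries and whose mean signal is at or above the median. Part 2 does the same for lower regions. Part 3 takes from each list up to 4 genes, those whose region has the smallest adjusted p, whether or not it passes. Each value given for such a gene is that of this 1 region, and its other regions can differ. Part 4 takes the region of highest mean signal at Nr4a1, Nr4a2, Nr4a3, Gt(ROSA)26Sor, Myh6 and A1cf. Items chosen after their values were seen are marked as such.

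The total signal was compared with an exact permutation test of the difference in mean log2 total CPM. Alternatives covered the scaling (TMM, median-of-ratios factors, column totals), the tool (DESeq2 version 1.42.0 on recovered reads), filters on low regions, thresholds, a pseudocount of 5, a block for the mouse number and leaving out each mouse. edgeR on recovered reads, recovered reads without scaling and a fold threshold at the natural logarithm of 2 were added after the data had been seen. A search for the NR4A binding motif in the regions was planned and not run, because it needs a genome sequence. Tables were handled in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.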

Results

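NR4A2 is a nuclear receptor that binds DNA without a known natural ligand, and the study asked where it binds in the heart when it is switched on in cardiomyocytes. NR4A2 ChIP-seq signal was compared between 3 hearts of mice with tamoxifen-induced NR4A2 and 3 hearts of control littermates that carry the Cre recombinase alone, 3 days after tamoxifen. The values are the authors' CPM, reads scaled to the depth of each library, in 16884 regions (build GRCm38), 192 to 34918 bp long with a median of 438 bp, on 20 chromosomes. Of these regions, 13251 (78.5%) overlapped the span of a protein-coding gene. Reads in regions ranged from 549700 to 1027394 in the control hearts and from 637635 to 1035856 in the NR4A2 hearts. Across regions, the correlation of log2(CPM + 1) was 0.877 to 0.913 among control hearts, 0.824 to 0.857 among NR4A2 hearts and 0.645 to 0.760 between the groups. Regions are not independent replicates. Mice are the replicates, and n = 3 in each group throughout.

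Relative to all reads in regions, signal differed between the groups in both directions, with more regions higher than lower. Signal was higher in NR4A2 hearts in 2475 regions (14.7% of those tested) and lower in 536 (3.17%). DESeq2 on recovered reads gave 2219 and 234, and the test limited to the 8442 regions of at least median signal gave 481 and 235. The median of the higher regions was 9.70 CPM in control hearts and 38.8 CPM in NR4A2 hearts, and 42.6% of them changed at least 4-fold (a log2 fold change of 2). The lower regions started from a stronger signal and changed less, from a median of 95.8 CPM to 57.3 CPM. The median log2 fold change was 1.87 in higher, -0.76 in lower and -0.13 in uncalled regions. Higher regions held 4.58 to 5.10% of the CPM of each control heart and 12.6 to 15.1% of that of each NR4A2 heart. With totals held equal, this larger share lowers all other regions, and lower regions were tested against 0. Part of each fall may come from this, and how much was not tested. Without NR4A2 mouse 3 the counts were 1577 and 270, and without control mouse 3 they were 2332 and 354. With no scaling for depth the counts were 1391 and 14. The median log2 fold change of the regions called lower was then -0.78, but leaving out the scaling shifts all folds by about the same amount. That median is therefore no check of the losses.

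**Figure D1:**
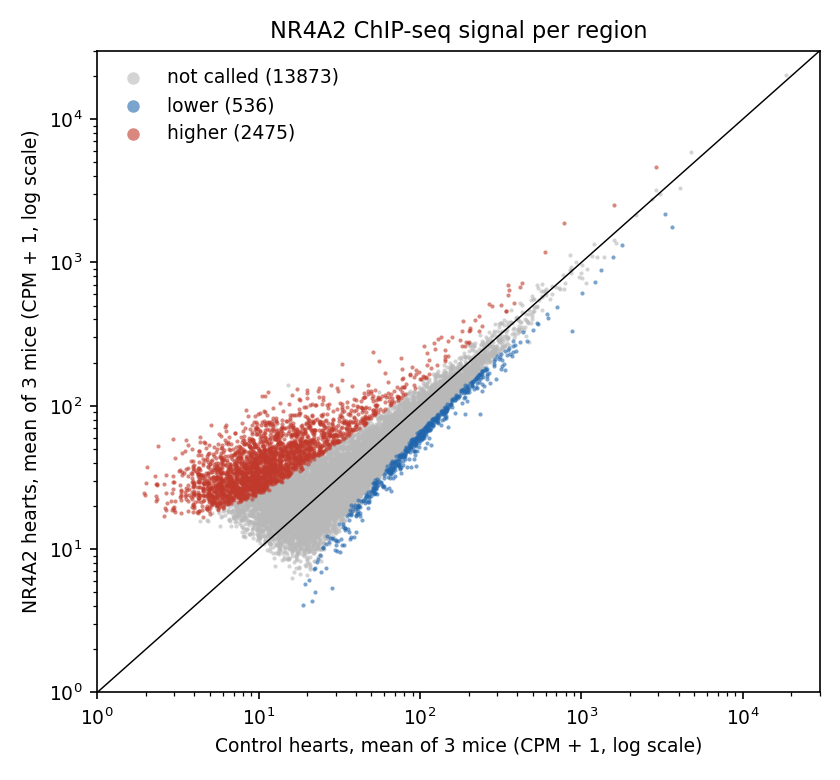
Mean NR4A2 ChIP-seq signal of each of the 16884 regions in 3 control hearts (x axis) and 3 NR4A2 hearts (y axis), as CPM + 1 on log scales, with the line of equal signal. The 2475 higher regions (red) lie mostly at low control signal, and the 536 lower regions (blue) at higher control signal.

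The strongest gains among regions of at least median signal lay at genes of varied function. At Plcb4, a phospholipase C of the signalling pathway of Gq-coupled receptors, a region within the gene (chromosome 2, 135848082 to 135848604) went from 6.93 ± 6.82 CPM in control hearts to 75.05 ± 12.98 CPM in NR4A2 hearts (SD, n = 3), a log2 fold change of 3.94 ± 0.85 (SE, adjusted p = 0.0106). Control mouse 3 had 0 reads there, and the log2 fold change was 2.78 without that mouse and 4.72 without control mouse 2. With edgeR on recovered reads it was 3.20, below the 3.61 of Eif5a2, so the order of these genes depends on the method. At Eif5a2, a translation factor, a region within the gene (chromosome 3, 28795043 to 28795381) went from 5.28 ± 3.23 to 72.8 ± 10.3 CPM (log2 fold change 3.71 ± 0.45, adjusted p = 4.93e-10). At Angpt2, which encodes the vascular growth factor angiopoietin 2, a region within the gene (chromosome 8, 18695647 to 18696167) went from 9.19 ± 4.62 to 87.5 ± 12.99 CPM (log2 fold change 3.20 ± 0.37, adjusted p = 1.56e-10). This region is also assigned to Mcph1. The region at Nek3, a kinase gene (chromosome 8, 22141587 to 22142420), reached 118.0 ± 19.6 CPM from 15.2 ± 10.2 CPM. The other genes taken by the rule were E130311K13Rik (log2 fold change 3.44 ± 0.45 SE), Ano4 (3.32 ± 0.40), Akip1 (3.18 ± 0.42), Ank3, which encodes ankyrin-G (3.12 ± 0.39), Tmem98 (3.10 ± 0.42) and Tpbgl (3.02 ± 0.36). The regions named for E130311K13Rik, Tmem98 and Tpbgl lay 1949, 1349 and 6723 bp outside the gene.

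Lower signal at regions of at least median strength was led by Lrrc2 and Fabp3. At Lrrc2 (chromosome 9, 110953326 to 110955593) the signal was 236 ± 26.3 CPM in control hearts and 86.3 ± 21.4 CPM in NR4A2 hearts (log2 fold change -1.46 ± 0.19 SE, adjusted p = 4.89e-09). At Fabp3, the fatty acid binding protein of heart muscle (chromosome 4, 130309965 to 130317117), it was 875 ± 145 and 332 ± 58.2 CPM (log2 fold change -1.40 ± 0.15, adjusted p = 1.76e-11). The region at Cish, a gene of the family that restrains cytokine signalling (chromosome 9, 107299523 to 107301015), went from 116 ± 12.9 to 52.7 ± 21.0 CPM. The region at Rrad, which encodes a small GTPase that restrains the cardiac calcium channel (chromosome 8, 104630851 to 104631349), went from 75.5 ± 10.002 to 32.8 ± 2.19 CPM, while 1 of the 4 regions at Rrad was higher. The further genes were Sox4 (log2 fold change -1.38 ± 0.31 SE), Brf1 (-1.35 ± 0.32), Mmd (-1.22 ± 0.32), Ltn1 (-1.21 ± 0.35), Dtx3 (-1.17 ± 0.28) and the nuclear receptor coactivator gene Ncoa2 (-1.17 ± 0.28). The region named for Sox4 lay 4799 bp outside the gene, and the Fabp3 region also overlaps Zcchc17. Those named for Lrrc2, Cish, Rrad, Ltn1 and Dtx3 are also assigned to other genes. Without control mouse 3 the calls at Mmd, Ltn1 and Ncoa2 ended, with adjusted p of 0.0621, 0.0749 and 0.0539. The call at Ltn1 also ended without NR4A2 mouse 1.

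**Figure D2:**
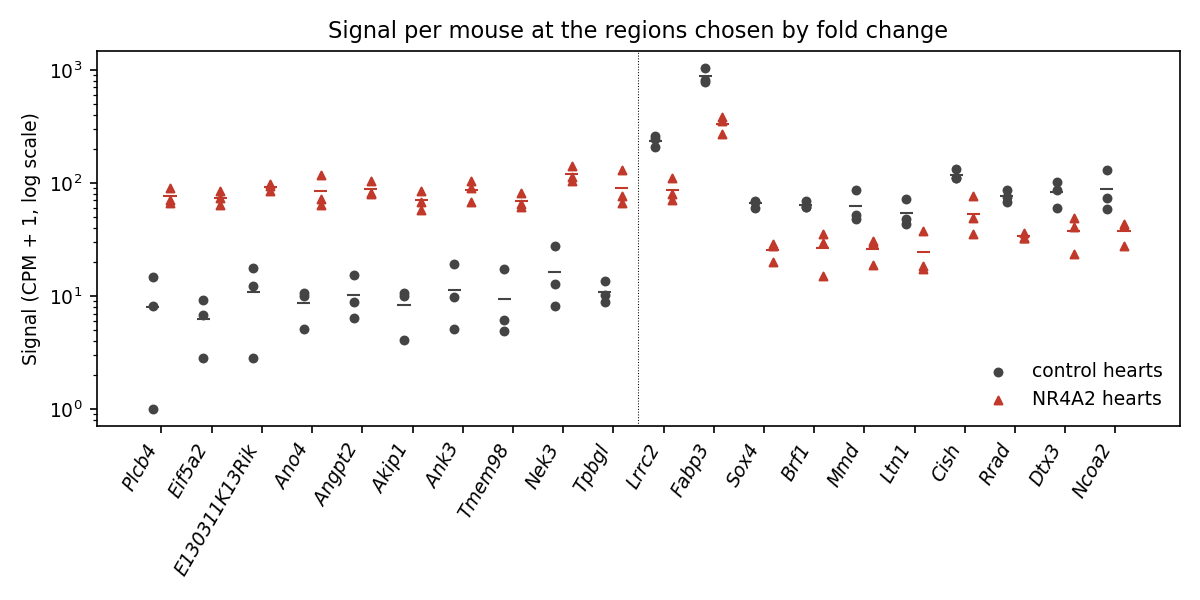
Signal per mouse (CPM + 1, log scale) at the 10 regions with the highest and the 10 with the lowest log2 fold change chosen by the rule; circles are control hearts, triangles NR4A2 hearts and short lines the group means (n = 3). At each of these regions the groups do not overlap, as the rule requires.

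Higher and lower regions differed in where they lay. Higher regions were short, with a median length of 369 bp, and lay a median of 25.04 kb from the nearest gene end. Of them, 188 (7.60%, 95% Wilson interval 6.62 to 8.71%) lay within 1 kb of a gene end, against 55.1% of all other regions (odds ratio 0.0669, 95% interval 0.0575 to 0.0779). Set against regions drawn from the same quartiles of mean signal, the share was 7.60% against 42.9% (Fisher's exact test, two-sided, p = 2.66e-274). Still, 59.8% of the higher regions overlapped a gene span, and 29.6% lay over 10 kb from any protein-coding gene. Lower regions were longer, with a median of 739 bp, and lay a median of 71 bp from a gene end. Within 1 kb of a gene end were 327 of them (61.0%, interval 56.8 to 65.0%), against 54.9% of uncalled regions (odds ratio 1.29, 95% interval 1.08 to 1.53, Fisher's exact test, p = 0.00529). Against uncalled regions from the same quartiles of mean signal the share was lower, 61.0% against 68.1% (odds ratio 0.732, Fisher's exact test, p = 0.000907), so no excess near gene ends remained at like signal. Both comparisons of lower with uncalled regions were chosen after the data had been seen.

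**Figure D3:**
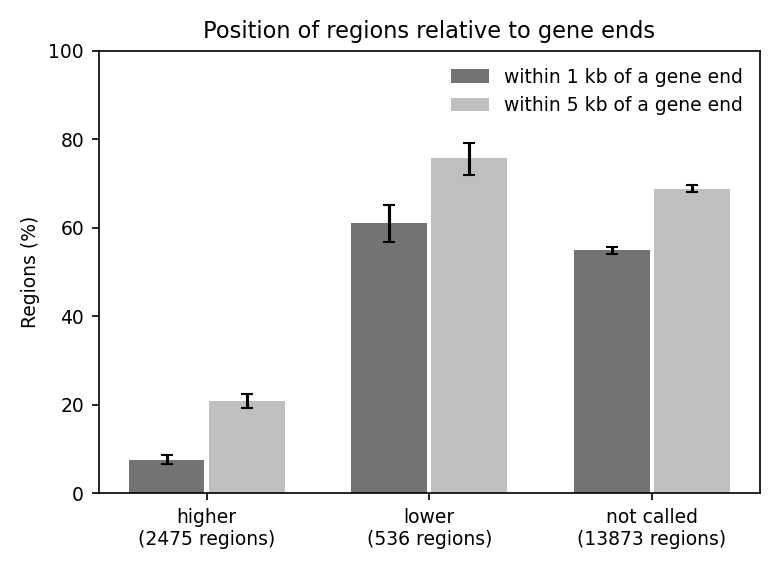
Percentage of higher, lower and uncalled regions within 1 kb (dark bars) and 5 kb (light bars) of either end of a protein-coding gene; error bars are 95% Wilson intervals over regions. The share within 1 kb was 7.60% for higher, 61.0% for lower and 54.9% for uncalled regions.

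Of 11155 genes with a region, 1583 (14.2%) had at least 1 higher region and 697 (6.25%) at least 1 lower region. Genes of the contractile apparatus had a called region more often than this in both directions before the number of their regions was allowed for. Among 30 sarcomere genes with a region, 19 had a higher region (odds ratio 10.6, Fisher's exact test, adjusted p = 1.68e-08) and 7 a lower one (adjusted p = 0.0217). Random lists with as many regions per gene held 13.7 and 5.07 on average, and against them neither call held (adjusted p = 0.417 and 1.00). The named members all had a higher region: Smyd1, a muscle methyltransferase needed for sarcomere assembly (log2 fold change 2.94 ± 0.39 SE), Ldb3, a Z-disc protein (1.06 ± 0.18), Csrp3, the muscle LIM protein (1.02 ± 0.15), and Actc1, cardiac actin (1.00 ± 0.19). Of 21 calcium handling genes with a region, 7 had a higher region (adjusted p = 0.0568) and 6 a lower one (adjusted p = 0.0217). The call for lower regions did not hold against matched random lists (adjusted p = 1.00) and ended whichever mouse was left out. Signal rose at Cacna1c, the pore of the L-type calcium channel (2.70 ± 0.37), Trdn, triadin (1.21 ± 0.21), and Slc8a1, the sodium-calcium exchanger (0.82 ± 0.20), and fell at Atp2a2, the calcium pump of the sarcoplasmic reticulum (-0.61 ± 0.14). At Atp2a2, 6 of 9 regions were lower and none was higher, and at Cacna1c 4 of 16 regions were higher and 1 was lower. At Trdn 4 of 24 and at Slc8a1 3 of 12 regions were higher. Of 16 genes of ion channels and conduction with a region, 6 had a higher (adjusted p = 0.0544) and 3 a lower region (adjusted p = 0.389). Signal rose at Cacna1h (3.24 ± 0.65), Kcnj5 (1.38 ± 0.24) and Kcnh2 (0.86 ± 0.19) and fell at Gja1, which encodes the main gap junction protein of the ventricle (-0.90 ± 0.16), where 6 of 9 regions were lower. At Kcnj5 3 of 7 and at Kcnh2 1 of 4 regions were higher. Control mouse 3 had 0 reads in the Cacna1h region, and without that mouse the log2 fold change there was 2.30.

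Among genes of fuel use, those of glucose metabolism gained regions most often. Of 32 such genes with a region, 16 had a higher region (odds ratio 6.10, Fisher's exact test, adjusted p = 1.66e-05) and 1 a lower one (adjusted p = 1.00). Random lists with as many regions per gene held 7.65 genes with a higher region on average, and the list stood above them (adjusted p = 0.0252). This comparison with random lists was not repeated with a mouse left out. Named members were Pfkm, muscle phosphofructokinase (log2 fold change 2.80 ± 0.33 SE), Gpi1 (2.60 ± 0.37), Slc2a4, the insulin-responsive glucose transporter (2.33 ± 0.30), and Eno3, muscle enolase (1.27 ± 0.14). Regions called higher were 6 of 12 at Pfkm, 1 of 4 at Gpi1, 3 of 5 at Slc2a4 and 1 of 6 at Eno3. The Eno3 region (chromosome 11, 70653609 to 70665155) also lies near Pfn1, Camta2 and other genes. In the fatty acid oxidation list, 7 of 32 genes had a higher region (adjusted p = 0.392) and 3 a lower one (adjusted p = 0.858). Signal rose at the coactivator genes Ppargc1a (1.95 ± 0.35) and Ppargc1b (1.53 ± 0.19) and at Ucp3 (1.25 ± 0.29), and fell at Fabp3. Of 32 genes of oxidative phosphorylation, 3 had a higher (adjusted p = 0.757) and 2 a lower region (adjusted p = 1.00). Values were 1.62 ± 0.39 at Sdhd, 1.58 ± 0.52 at Ndufs4, -0.67 ± 0.21 near Ndufv1 and -0.44 ± 0.14 at Slc25a4. The region named for Ndufv1 lies 6606 bp outside that gene and overlaps another gene. The calls at Ndufs4, Ndufv1 and Slc25a4 each ended with any of 3 or 4 of the 6 mice left out, with adjusted p of up to 0.0961, 0.0841 and 0.198.

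Among regulators of transcription, 9 of 21 cardiac transcription factor genes had a higher region (odds ratio 4.56, Fisher's exact test, adjusted p = 0.00935) and 2 a lower one (adjusted p = 0.800). The call for higher regions did not hold against matched random lists (adjusted p = 0.417), without NR4A2 mouse 3 or without control mouse 3. Signal rose at Tead1, at 1 region (log2 fold change 2.47 ± 0.53 SE) beside another that was lower, Irx4, a ventricle-specific homeobox gene (2.24 ± 0.38), and Tbx20 (1.76 ± 0.38). Of 29 genes of nuclear receptors and their partners, 9 had a higher region (adjusted p = 0.0544) and 4 a lower one (adjusted p = 0.437). Signal rose at 1 or more regions of Nr3c2, the mineralocorticoid receptor gene (3.63 ± 0.76), Rora (2.76 ± 0.47), Ncor1 (2.67 ± 0.61) and Nr2c2 (2.56 ± 0.52). Regions called higher were 1 of 5 at Nr3c2, 4 of 8 at Rora, 1 of 3 at Ncor1 and 1 of 2 at Nr2c2. Of 6 steroid and metabolic genes known as NR4A targets that had a region, 4 had a higher one (odds ratio 12.1, adjusted p = 0.0200) and 0 a lower one. Matched random lists held 1.72 on average, and against them the call did not hold (adjusted p = 0.417). These genes were Fbp1, a gluconeogenic enzyme gene (3.35 ± 0.66), Slc2a4, Lpin1, a regulator of lipid metabolism (1.33 ± 0.24), and Eno3; Slc2a4 and Eno3 are also in the glucose list, and the Fbp1 region lies nearer to Fbp2, which is in that list too. With 1 mouse left out, the log2 fold change at the Fbp1 region was 2.25 to 4.17. Of 8 genes reported as NR4A2 targets in neurons, 2 had a higher region (adjusted p = 0.476) and 0 a lower one, with Bdnf at 3.00 ± 0.40 and Ptpru at 1.97 ± 0.62. Nrp1 (-0.52 ± 0.22, adjusted p = 0.0994) and Drd2 (0.51 ± 0.22, adjusted p = 0.103) did not pass. The call at Ptpru ended with any of 3 mice left out (adjusted p up to 0.126).

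The list of fetal and stress genes of the heart had a higher region at 8 of 20 genes (odds ratio 4.05, Fisher's exact test, adjusted p = 0.0200) and a lower one at 2 (adjusted p = 0.800). Matched random lists held 4.64 genes with a higher region on average, and against them the call did not hold (adjusted p = 0.417). Signal rose near the atrial myosin gene Myl7 (log2 fold change 3.31 ± 0.62 SE), Ccn1 (2.09 ± 0.46) and Nppb, which encodes brain natriuretic peptide (0.77 ± 0.18), and fell near Nmrk2 (-1.07 ± 0.21). Of 22 genes of autophagy and proteolysis, 6 had a higher (adjusted p = 0.241) and 3 a lower region (adjusted p = 0.543), with Foxo3 (2.63 ± 0.42), Ulk1 (2.20 ± 0.55), Map1lc3a (1.60 ± 0.28) and Fbxo32 (1.38 ± 0.37) named for higher regions. Ulk1 also had 1 lower region and Fbxo32 had 2. Of 15 genes of the integrated stress response and serine synthesis, 2 had a higher (adjusted p = 1.00) and 1 a lower region (adjusted p = 1.00). Values were 1.70 ± 0.47 at Trib1, 1.08 ± 0.27 at Ddit3, -0.74 ± 0.27 at Mthfd1l and 0.51 ± 0.20 at Ppp1r15a, which did not pass (adjusted p = 0.0690). Of 17 circadian clock genes, 2 had a higher region (adjusted p = 1.00), Rora and Cry2 (1.07 ± 0.36), and 0 a lower one. Tef (-0.49 ± 0.19, adjusted p = 0.0561) and Per1 (-0.52 ± 0.21, adjusted p = 0.0635) did not pass. The calls at Ulk1, Ddit3, Mthfd1l and Cry2 ended with at least 1 of the mice left out (adjusted p up to 0.0506, 0.0562, 0.340 and 0.0986).

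None of the growth, damage and inflammation lists passed the test in either direction. Of 25 cell cycle genes, 1 had a higher region (Fisher's exact test, adjusted p = 0.428), Rb1 (log2 fold change 2.12 ± 0.37 SE), and 3 a lower one (adjusted p = 0.597), namely Ccnd3 (-1.84 ± 0.55), Ccnd2 (-0.71 ± 0.25) and Rbl1 (-0.64 ± 0.22). The 3 lower calls ended with at least 1 mouse left out (adjusted p up to 0.118, 0.207 and 0.255). Of 20 genes of the p53 response and DNA repair, 0 had a higher region (adjusted p = 0.234) and 1 a lower one (adjusted p = 1.00), Brca1 (-0.87 ± 0.27), whose call ended without NR4A2 mouse 3 (adjusted p = 0.143) and without control mouse 1. Ccng1 (1.00 ± 0.46, adjusted p = 0.131), Gadd45g (0.53 ± 0.23, adjusted p = 0.117) and Sesn1 (-1.07 ± 0.50, adjusted p = 0.138) did not pass. Of 14 inflammation genes, 1 had a higher (adjusted p = 0.826) and 1 a lower region (adjusted p = 1.00), both at Nfkb1 (3.00 ± 0.46 for the region named). Il6st (1.73 ± 0.71, adjusted p = 0.0780), Irf1 (-0.50 ± 0.20, adjusted p = 0.0731) and Rela (-0.40 ± 0.18, adjusted p = 0.120) did not pass.

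Marker lists of the other cell types of the heart did not pass the test in either direction. Of 7 fibroblast markers with a region, 0 had a higher (Fisher's exact test, adjusted p = 0.757) or a lower one. Values were -0.59 ± 0.24 at Tgfb1 (log2 fold change ± SE, adjusted p = 0.0844), -0.46 ± 0.22 at Vim (adjusted p = 0.137), -0.50 ± 0.41 at Col1a1 (adjusted p = 0.458) and 0.20 ± 0.41 at Col3a1 (adjusted p = 0.798). Of 17 endothelial markers, 2 had a higher (adjusted p = 1.00) and 4 a lower region (adjusted p = 0.131): Vwf (2.10 ± 0.36) and Esam (1.32 ± 0.38) against Fli1 (-0.75 ± 0.22), Pecam1 (-0.69 ± 0.24), Tie1 and Sox18. Of 4 macrophage and leukocyte markers, Itgam had a higher region (1.96 ± 0.48) and Spi1 a lower one (-1.05 ± 0.26), which also lies near the sarcomere gene Mybpc3. The adjusted p of that list was 0.641 for higher and 0.597 for lower regions. Cd68 (-0.32 ± 0.16, adjusted p = 0.156) and Cd14 (-0.05 ± 0.21, adjusted p = 0.898) did not pass. Of 8 smooth muscle and pericyte markers, 2 had a higher region (adjusted p = 0.476), Notch3 (1.38 ± 0.26) and Synpo2 (1.44 ± 0.49), and 0 a lower one; Mylk (0.58 ± 0.23, adjusted p = 0.0613) and Pdgfrb (0.82 ± 0.38, adjusted p = 0.128) did not pass. The calls at Esam, Pecam1, Itgam, Spi1 and Synpo2 ended with at least 1 mouse left out (adjusted p up to 0.0961, 0.291, 0.0923, 0.0663 and 0.147).

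Of the 5 lists that passed for higher regions, glucose metabolism alone also passed against random lists matched on regions per gene, and of the 2 that passed for lower regions neither did. The matched comparison was run only on the limma calls from all mice. The counts of lists with a mouse left out are from Fisher's exact test without matching. Without NR4A2 mouse 3 and without control mouse 3 the counts for higher regions were 4 and 6. The number of lists with higher regions was 8 without control mouse 1 and 8 without NR4A2 mouse 1, against 5 with all mice. For lower regions, 0 lists passed without control mouse 1, control mouse 2 or NR4A2 mouse 3, and sarcomere alone passed without control mouse 3 or NR4A2 mouse 1. Without NR4A2 mouse 2, sarcomere passed and so did autophagy, which did not with all mice. Adjusted over the list alone, the number of members with a higher region was equal in 19 lists and differed in ion channels (7) and oxidative phosphorylation (1). For lower regions it was equal in 13 lists and differed in sarcomere (6), ion channels (4), fatty acid oxidation (2), oxidative phosphorylation (0), cell cycle (1), integrated stress (0), autophagy (4) and endothelial markers (1).

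**Figure D4:**
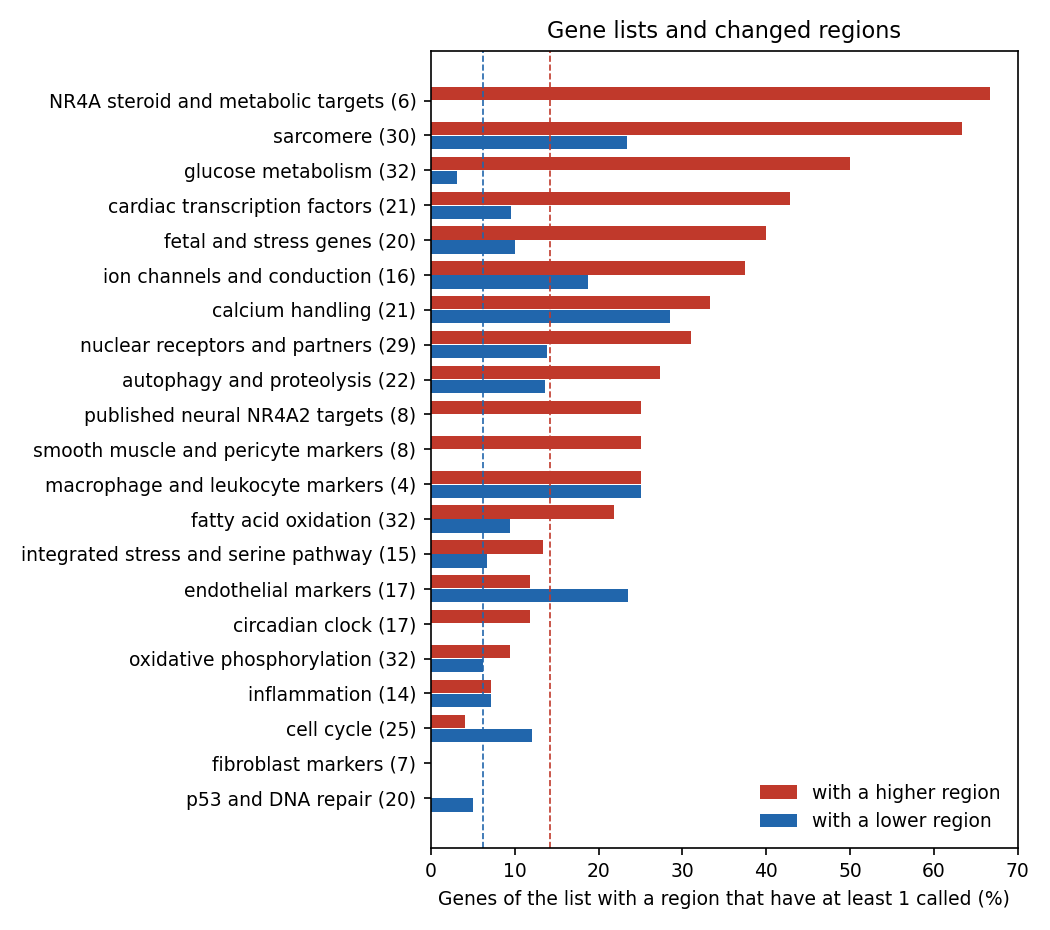
Percentage of the genes of each list that have at least 1 higher region (red) or at least 1 lower region (blue), among the genes of the list with any region (number in brackets); dashed lines are the shares among all 11155 genes with a region, 14.2% and 6.25%. Glucose metabolism reached 50% for higher and sarcomere 63.3%.

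Of the strongest regions at the NR4A family and the loci of the transgenes, only that at Nr4a1 was called. At Nr4a1 the strongest region (chromosome 15, 101266492 to 101267024) was lower in NR4A2 hearts, at 47.5 ± 8.90 CPM against 83.7 ± 24.8 CPM (SD, n = 3; log2 fold change -0.77 ± 0.26 SE, adjusted p = 0.0241). That call ended with any of 4 mice left out (adjusted p up to 0.141). At Nr4a2 itself the strongest region (chromosome 2, 57116606 to 57117270) held 74.9 ± 2.91 CPM in control hearts and 71.6 ± 17.6 CPM in NR4A2 hearts (log2 fold change -0.09 ± 0.24, adjusted p = 0.837). Values at the region near Nr4a3 were 122 ± 13.9 and 100.4 ± 36.5 CPM (adjusted p = 0.288), and at Gt(ROSA)26Sor, into which the transgene was inserted, 308 ± 23.6 and 373 ± 27.7 CPM (adjusted p = 0.226). The other 2 of the 3 regions at Gt(ROSA)26Sor were both higher in NR4A2 hearts, the stronger of them (chromosome 6, 113072670 to 113075973) at 291 ± 34.7 against 128 ± 18.0 CPM (log2 fold change 1.18 ± 0.17 SE, adjusted p = 1.01e-07). The inserted transgene is present at this locus in NR4A2 hearts alone, and its effect on reads there was not tested. The region over Myh6 and part of Myh7, the cardiac myosin heavy chains (chromosome 14, 54936655 to 54971572), held the most signal of all regions, 18489 ± 4107 CPM in control hearts and 20444 ± 2088 CPM in NR4A2 hearts (adjusted p = 0.494). No listed region lay within 10 kb of A1cf.

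Total signal over all regions did not differ, which the scaling of the table brings about. The mean log2 total CPM differed by -0.0038 between NR4A2 and control hearts (exact permutation test, two-sided, p = 0.700, the smallest possible being 0.1). Over the 13873 uncalled regions the difference was -0.10 (exact permutation test, p = 0.1), with all 3 NR4A2 hearts below all 3 control hearts. With totals held equal, the larger share of the higher regions lowers the rest by construction, so this value shows no loss. The same construction acts on the regions called lower.

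In the authors' deposited table, 2521 regions were called up and 329 down. Of these calls, 2392 higher and 296 lower ones were also made by limma on the same values, and 0 had the opposite direction.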

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

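edgeR on recovered reads, recovered reads without scaling, the fold threshold at the natural logarithm of 2, and the list and position results with other calls were chosen after seeing the data. The larger number of higher than lower regions held in all settings run. Higher and lower regions numbered 2574 and 579 with edgeR on recovered reads, 2448 and 585 with median-of-ratios factors, and 2594 and 588 with a pseudocount of 5. TMM factors equal the deposited scaling, and the filter of at least 10 CPM in at least 3 libraries removed no region, so neither tests anything. Counts beyond 1.5 times the reported ones were 481 and 235 with the 8442 regions at or above the median signal, a smaller set. They were also 1391 and 14 with no scaling for depth, and 1577 and 270 without NR4A2 mouse 3. For lower regions alone they were 354 without control mouse 3 (2332 higher) and 234 with DESeq2 (2219 higher). By threshold, lower regions numbered 125 at a log2 fold change of at least 1 and 326 at one of at least ln 2. At an adjusted p under 0.1 they numbered 927. The thresholds act by construction, and the cause of the other counts was not tested. With no scaling, the median log2 fold change was 1.83 in regions called higher and -0.78 in those called lower, against 1.87 and -0.76 with scaling. Leaving out the scaling shifts all folds by about the same amount, so these medians are no check of the gains or losses. They show only that smaller folds do not account for the calls lost without scaling. With 1 mouse left out, higher regions numbered 1577 to 2332 and lower ones 270 to 454, the lowest in both cases without NR4A2 mouse 3.

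With mouse number as a replicate block, counts were 2540 and 580 (2502 and 521 in edgeR with the block). Deviations of same-numbered mice correlated at -0.0658, 0.0609 and 0.0326, so the numbers pair no mice, and not every mouse correlated best with its own number. The block gave an odds ratio of 0.0687 for gene ends, 6 lists with higher and 2 with lower regions. It ended no call at a named region and added 1, at Tef (adjusted p = 0.0414).

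The odds ratio for lying near a gene end was 0.0638 to 0.0728 with 1 mouse left out, 0.117 within 5 kb, 0.110 in matched quartiles of signal and 0.0662 with edgeR calls. Lists past the threshold for higher regions numbered 5, with 4 to 8 when 1 mouse was left out, 4 with regions at gene ends, 7 with edgeR calls and 1 against matched random lists. For lower regions they numbered 2, with 0 to 2 when 1 mouse was left out, 1 with edgeR calls and 0 against matched random lists; the cause was not tested. The difference in total signal was -0.0084 to 0.0031 on the log2 scale with 1 mouse left out, changing sign without control mouse 1 and without NR4A2 mouse 1. Of 105 named regions, 61 of the 82 called kept their call in each fit with 1 mouse left out. Sign changed at 3 uncalled ones, with ranges of -0.21 to 0.0802 at Cd14, -0.24 to 0.12 at Nr4a2 and -0.0110 to 0.32 at Myh6. The motif result was not run, since it needs a genome sequence. Depth limits regions with little signal: 3 reads in the shallowest library equal 5.43 CPM, against a median of 9.70 CPM for higher regions in control hearts, so their folds are imprecise.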

Other observations

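The items in this part were chosen after their values were seen, and so were its tests, apart from those at equal depth. Several genes outside the lists held many higher regions. All 6 regions at Creb5, a transcription factor gene, were higher, as were all 5 at Fto, which encodes an RNA demethylase. At Cdhr3 7 of 9 regions were higher, at Auh, a leucine catabolism gene, 5 of 6, and at Rptor, a subunit gene of the growth regulator mTORC1, 5 of 8. At Lpin1 6 of 9 and at Pfkm 6 of 12 regions were higher, while Ttn, the titin gene, had 9 higher regions among 183. In all, 112 genes had at least 3 higher regions. The genes with most lower regions were Atp2a2 and Gja1 (6 of 9 each) and Ckm, muscle creatine kinase (5 of 5). Both a higher and a lower region were present at 66 genes.

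Some regions of at least 5 kb lay over noncoding RNA genes. A region of 18969 bp over Mir1a-1, Mir133a-2 and their host transcript (chromosome 2, 180385428 to 180404396) fell from 3650 ± 665 to 1771 ± 609 CPM (SD, n = 3; log2 fold change -1.09 ± 0.25 SE, limma adjusted p = 0.0109). The paralogous cluster with Mir1a-2 and Mir133a-1 within Mib1 held 1372 ± 302 and 1090.1 ± 242 CPM (log2 fold change -0.33 ± 0.15, adjusted p = 0.136), and the difference between the 2 clusters was not tested. Regions over the long noncoding RNA genes Malat1 (log2 fold change -0.02 ± 0.14, adjusted p = 0.934) and Neat1 (-0.31 ± 0.14, adjusted p = 0.128) did not pass.

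Within Nr4a2 other regions did differ. One (chromosome 2, 57111638 to 57112257) held 13.1 ± 10.6 CPM in control and 90.3 ± 21.3 CPM in NR4A2 hearts (log2 fold change 2.92 ± 0.37 SE, limma adjusted p = 8.9e-09). The NR4A2 hearts alone carry the Nr4a2 transgene. Reads from the transgene placed at this gene cannot be told apart here from binding at the gene itself. On chromosome 19, a run of 10 regions spanned 23.7 kb (31828179 to 31851916), ending 16840 bp from A1cf, a gene named in the designation of the Cre strain, and was present in both groups, with 3 of its regions higher in NR4A2 hearts. In the authors' deposited table, the smallest called change was 0.694 and the largest uncalled one with FDR under 0.05 was 0.693 on the log2 scale, which is the natural logarithm of 2 (0.693, a fold of 1.62). With an absolute log2 fold change of at least 1, that table would hold 2382 up and 133 down.

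Higher regions were short, far from gene ends and weak in control hearts. Unequal depth was argued against: with every library thinned to 549700 reads, 84.0% of these regions were still called (median of 10 draws). Dependence on NR4A2 mouse 3, the mouse whose removal lowered the count most, was argued against too, since without it 7.04% of higher regions lay within 1 kb of a gene end against 52.4% of the others. A list of regions drawn mainly from NR4A2 libraries may contribute and cannot be told apart from gained binding. The number of regions with at most 3 reads in each control library was 49. The number with at most 3 reads in each NR4A2 library was 0. The rule for drawing regions is not given in the sources used here. New binding of induced NR4A2 at distal sites stays open as a hypothesis, without a motif test.

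Lower regions included those at the heart muscle genes Atp2a2, Fabp3, Mb and Gja1, which were picked as examples. Of 1080 regions within 10 kb of a gene of the cardiomyocyte lists, 43 were lower, 141 higher and 896 not called. Among all regions tested, 3.17% were lower and 14.7% higher. No gene list passed for lower regions against matched random lists, so a concentration of losses at heart muscle genes was not shown. At equal depth 57.3% of all lower regions were still called, which argues against unequal depth as the whole cause. The larger share of the higher regions lowers all others by construction, with a median log2 fold change of -0.13 in uncalled regions. Lower calls, the weakest at -0.43, were tested against 0. How many of them come from this shift was not tested. A smaller share of cardiomyocytes in NR4A2 hearts would lower their genes together. Of 28 regions of at least 5 kb at genes of the cardiomyocyte lists, 8 were higher and 7 lower. These counts cannot exclude a smaller share, since gains from NR4A2 induced in cardiomyocytes could offset such a fall. A rise over all regions hidden by the scaling cannot be told apart from a true loss, since the median log2 fold change of the lower regions, -0.76, is relative to reads in regions and that without scaling, -0.78, includes depth. Lower transcription of the genes with lower regions could also give lower signal there and was not tested.

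Broad, strong signal was present in control hearts at genes such as Myh6, Pln, Tnnt2 and Actb. Signal that does not depend on NR4A2 may explain part of it: of 44 regions of at least 5 kb, 27 were not called, 8 were higher and 9 lower. Binding by the mouse's own NR4A2 that was already saturated would give the same, and the input libraries that bear on it were not analysed here, so these cannot be told apart.

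For the counts of 2475 higher and 536 lower regions, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest count in any other split was 0. With 10 splits the share cannot go under 0.1, so this is too few for a statement on chance.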
